A study of Homo sapiens with 28 samples.

How the data were processed

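Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers cross-linked chromatin with an antibody, sequences the bound DNA fragments and reports the places in the genome where fragments pile up, called peaks. The libraries came from GP5d, an established human colon adenocarcinoma cell line. Per the labels' protocols, the cells were transfected with 50 nM of a small interfering RNA (siRNA), a short duplex that directs the degradation of a matching messenger RNA, and were harvested after 72 hours. The siRNA targeted RAD21, a core subunit of the cohesin ring, or was a neutral control with no target. The group of each library was taken from its title and checked against its description. A separate siRNA tag in the labels named RAD21 for the siRAD21 CTCF library and the same stem with other, rising numbers for the other siRAD21 libraries, which conflicts with their titles and descriptions. Targets and antibody hosts were also taken from the titles. The catalogue number in the labels of the H3K4me1 libraries is, from general knowledge, that of an antibody to histone H3 whatever its modification, and that of the MYC libraries is that of a mouse antibody where the title names rabbit, so the antibody behind these libraries is not settled here.

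Of the 28 libraries, 22 had peak lists, 1 for each of 11 targets under each siRNA, and the other 6 were immunoglobulin G (IgG) libraries, which record the background of an immunoprecipitation without a specific antibody. IgG peaks were not analysed here. With 1 library per target and siRNA there was no replicate check of any difference between the siRNAs, no test between libraries was made, and all intervals cover counting error only.

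Reads were processed with CASAVA 1.4, BWA and MACS 1.4 on the hg18 build, per the submitters' processing notes. Peaks were called by the authors in each library on its own with MACS 1.4.0rc2, per the file headers, against the IgG library of the same siRNA and antibody host. CTCF and RFX2 were called against goat IgG and the other targets against rabbit IgG. The headers gave an effective genome size of 2.75e+09 bp, a p cutoff of 1e-05, a band width of 300 bp, a model fold range of 2 to 6 and 1 kept tag per position. MACS sets the tags in a window against a local background rate, taken from the IgG library within 1000 and 10000 bp, and scales the libraries to each other.

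Each peak had, per the file headers, a start, an end and a summit, a count of tags, a significance on the −10 × log10 p scale (50 and above), a fold enrichment (a linear ratio over the background) and a false discovery rate (FDR) in percent. The files held 10 columns under 9 names. The unnamed column was read as the FDR in percent because its number of values under 5 equalled the number of peaks that the labels give at FDR under 5% in all 22 libraries. Column 9 held values equal to or above those of the unnamed column and was not used to select peaks by FDR. These values per peak are the authors' own and mostly served to describe, rank or filter peaks within a list. Peaks of different targets were also matched by p, where RAD21 and SMC3 were set against other targets. The FDR comes from peaks called with ChIP and IgG exchanged, so it depends on the IgG library as well.

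Depth was read from the tags per library given in the deposited headers. After filtering of repeated positions, control ChIP libraries held 3629966 to 19926326 tags (median 9603820) and siRAD21 ChIP libraries 1747770 to 15263937 (median 7006171). The rabbit IgG libraries held 8916252 tags under control siRNA and 4101535 under RAD21 siRNA, and the goat IgG libraries 3914714 and 3293704.

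The following choices were made before the data were examined. All deposited peaks formed the main list. A control peak was called retained when a siRAD21 peak of the same target overlapped it by at least 1 bp, and lost otherwise. Shares were given with 95% Clopper-Pearson intervals. Chance overlap was the mean over 100 circular shifts of the second list along each chromosome. Differences in retained share between classes of peaks were averaged over 5 strata of the whole control list by p with Mantel-Haenszel weights, so that peaks of like strength were compared. Over the 7 factors CTCF, HNF4A, JUND, KLF5, MYC, REST and RFX2, the differences were tested with an exact two-sided sign-flip permutation test. That test speaks of these factors in this pair of treatments and not of replicate cultures, and all its values share the same RAD21 libraries. Peaks of the 6 factors other than CTCF were joined into clusters where they lay within 1000 bp. The regions to be named were, per target, the strongest retained control peak by p, the pair of strongest control peaks with no siRAD21 peak of that target within 1000 bp, the strongest siRAD21 peak with no control peak within 1000 bp, and the 5 clusters with the most factors. Regions of RAD21, SMC3, CTCF, HNF4A, KLF5 and MYC came first under a limit on their number. Those of REST were added later, after the results were seen, and those of NIPBL, H3K4me1, JUND and RFX2 are left out here.

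Alternatives covered stricter peak lists, equal list lengths, other definitions of overlap, other strata, other definitions of cohesin-bound peaks and other cluster gaps. The mean as the statistic of the sign-flip test and the smallest shift, 1000000 bp, were set when the analysis was written. A first run drew the strata within the RAD21-bound peaks, and this was replaced by strata of the whole list, as planned, with the first value kept as an alternative. The calculation of the overlap and stratified difference was tested on simulated data. Such a test does not show how far the strata remove the effect of peak strength in the real lists. With 11113 HNF4A peaks, a difference of 0 percentage points was recovered as 1.18 (95% interval −0.815 to 3.18), and one of 15 as 16.0 (14.0 to 18.0). Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Coordinates are those of hg18, counted from 1. No gene annotation of this build was used here, so regions are given without gene names and the gene lists planned for such an annotation were not used here.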

Results

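The data describe where cohesin, its loader, CTCF, a histone mark and 6 further transcription factors were found on chromatin in GP5d colon adenocarcinoma cells, with and without RAD21 siRNA. RAD21 and SMC3 are core subunits of cohesin, the ring that holds sister chromatids together and extrudes chromatin loops. NIPBL loads cohesin onto DNA, and CTCF is a zinc finger protein at which loop extrusion halts. Monomethylated histone H3 lysine 4 (H3K4me1) marks enhancers and the flanks of promoters. The libraries called H3K4me1 here were named by their titles, while the antibody number in the labels is known for general histone H3, so all H3K4me1 values carry that doubt. HNF4A is a nuclear receptor of intestinal and hepatic epithelium, KLF5 a zinc finger factor of the proliferating intestinal crypt, and JUND a member of the AP-1 family. MYC is a growth regulator, REST represses neuronal genes outside the nervous system, and RFX2 activates genes of the cilium. The series addresses how transcription factor binding is arranged around cohesin sites. The 22 peak lists held 235159 peaks under control siRNA and 158109 under RAD21 siRNA.

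The first comparison asked how many sites each protein occupied after RAD21 siRNA. RAD21, the target of the siRNA, had 36204 peaks under control siRNA and 19752 under RAD21 siRNA, a ratio of 0.546. Its partner SMC3 had 38799 and 12548 peaks, a ratio of 0.323, and the loader NIPBL had 11694 and 6068, a ratio of 0.519. CTCF had 44027 and 32196 peaks, a ratio of 0.731. RAD21 RNA and protein were not analysed here, so the knockdown itself was not measured.

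Among the other factors, KLF5 had the lowest ratio, with 7791 peaks under control siRNA and 1781 under RAD21 siRNA (0.229). MYC had 13589 and 7264 peaks (0.535), RFX2 2078 and 1158 (0.557), and HNF4A 11122 and 7082 (0.637). H3K4me1 had 61108 and 53581 peaks (0.877). REST had 4069 and 4360 peaks (1.07). JUND had 4678 and 12319 peaks (2.63). Of the 11 targets, 9 had fewer peaks under RAD21 siRNA. Leaving out JUND and NIPBL, whose control lists held no peak with an FDR under 5%, 8 of 9 had fewer.

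Sequencing depth moved with the siRNA. The siRAD21 ChIP library held fewer tags after filtering for 9 of the 11 targets, with a ratio of 0.615 for RAD21, 0.531 for SMC3, 0.346 for CTCF, 0.355 for KLF5 and 0.619 for REST. For MYC the ratio was 1.02, although before filtering its siRAD21 library held 26879136 tags and its control library 13545723, of which 64% and 29% were repeated positions. For JUND the ratio was 2.02. Ratios of peak numbers also differed between selections of peaks. For peaks with an FDR under 5%, SMC3 had 33726 and 3829 (0.114), MYC 13589 and 936 (0.0689), CTCF 34209 and 32196 (0.941), and the direction was the opposite for H3K4me1 (1.29) and RFX2 (1.28). Of the 9 targets with such a ratio, 6 had fewer peaks at that FDR, whereas 10 of 11 had fewer peaks with −10 × log10 p of at least 100, where REST had a ratio of 0.898. NIPBL had 0 and 1441 peaks with an FDR under 5% and JUND 0 and 718. Both thus had more under RAD21 siRNA but no ratio.

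**Figure D1:**
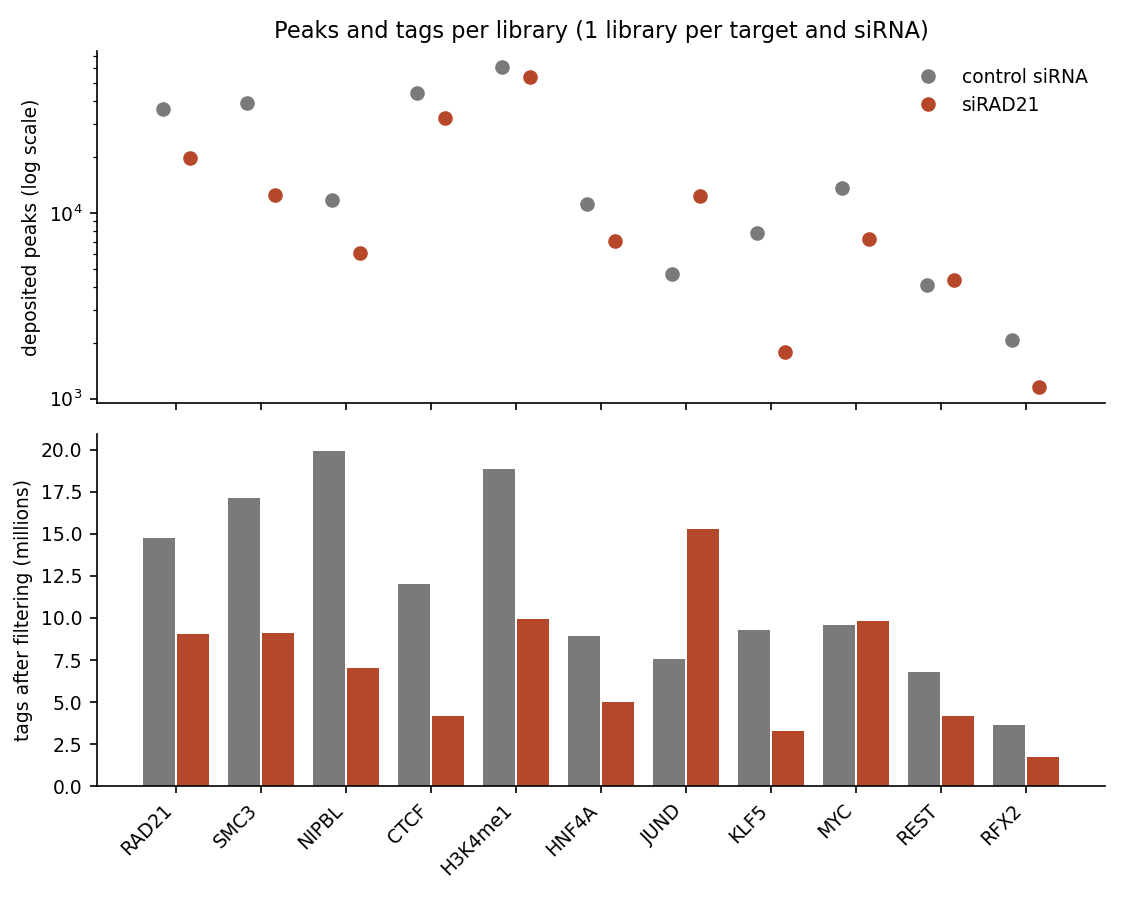
Deposited peaks on a log scale (upper panel) and number of ChIP tags after filtering (lower panel) for each of the 11 targets under control siRNA (grey) and RAD21 siRNA (red), 1 library each. JUND and REST are the targets with more peaks under RAD21 siRNA, and JUND and MYC those without a lower tag number.

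The second comparison followed individual sites. Among all deposited peaks, with overlap by at least 1 bp, H3K4me1, REST and CTCF had the highest retained shares. A siRAD21 peak overlapped 69.1% of the control REST peaks (95% interval 67.6 to 70.5, chance 0.590%) and 74.3% of the control H3K4me1 peaks (73.9 to 74.6, chance 11%). CTCF kept 63.1% of its peaks (62.6 to 63.5, chance 3.44%). RAD21 kept 46.6% (46.1 to 47.1, chance 1.93%) and SMC3 28.4% (27.9 to 28.8, chance 1.28%). NIPBL kept 17.4% (16.7 to 18.1).

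Retained shares of the factors spanned a wide range. JUND kept 35.1% of its peaks (33.7 to 36.5), HNF4A 33.4% (32.5 to 34.3), MYC 28.9% (28.2 to 29.7), RFX2 13.2% (11.8 to 14.7) and KLF5 10.2% (9.52 to 10.9). Seen from the siRAD21 lists, 86.3% of the RAD21 peaks and 88.3% of the SMC3 peaks overlapped a control peak of the same protein. REST had 65.4%, KLF5 45.1%, NIPBL 33.7% and RFX2 23.7%. JUND had 13.3%, a share limited by list length, since 12319 siRAD21 peaks were set against 4678 control peaks.

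Strong peaks were retained more often than weak ones. Among peaks with −10 × log10 p of 400 and above, REST kept 99.7%, H3K4me1 96.7%, CTCF 93.6%, HNF4A 92.3%, RAD21 88.7% and SMC3 68.1%. From 50 to 100, RAD21 kept 9.78%, SMC3 3.96% and REST 23.2%. KLF5 kept 64.5% of its strongest class and JUND 64.3%, the latter from 14 peaks. List length mattered as well. With equal numbers of the strongest peaks from both lists, CTCF kept 77.8%, RAD21 73.0%, REST 68.3%, SMC3 64.4%, KLF5 25.9%, RFX2 21.4% and JUND 17.6%, whereas at an FDR under 5% SMC3 kept 11.2%, KLF5 6.64% and MYC 6.15%. By summits within 250 bp H3K4me1 kept 42.6%, below REST at 64.5%, CTCF at 59.3% and RAD21 at 45.6%.

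**Figure D2:**
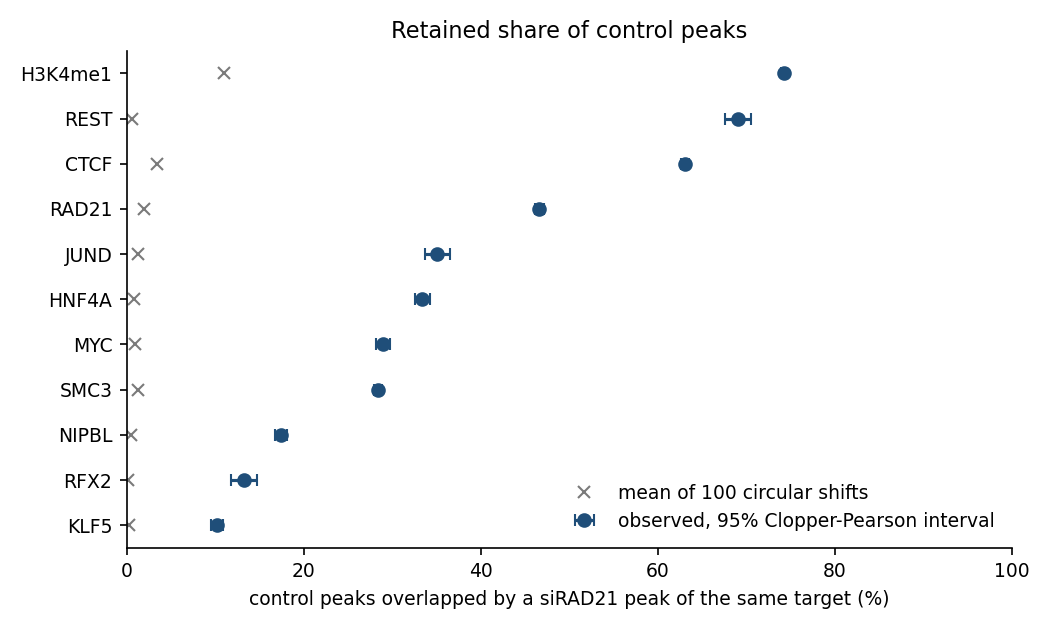
Share of control peaks overlapped by a siRAD21 peak of the same target, in percent (points, with 95% Clopper-Pearson intervals), and the mean of 100 circular shifts (crosses). H3K4me1, REST and CTCF lie above 60%, and KLF5 is lowest at 10.2%.

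Single regions show these patterns (hg18). The −10 × log10 p value 3233.06 recurred among the named peaks of SMC3, H3K4me1 and REST, and 3100 among those of MYC and H3K4me1. The scale may thus have a ceiling, and the strongest peaks are those by reported p only. The strongest retained RAD21 peak lay on chromosome 20 from 46669161 to 46672160, with −10 × log10 p of 3220 and a fold enrichment of 37.2. Control peaks of 7 targets were found there, and RAD21, SMC3, CTCF and H3K4me1 peaks were found under RAD21 siRNA. The strongest lost RAD21 peaks lay on chromosome 10 from 93836764 to 93838560 and from 85620554 to 85622428, with −10 × log10 p of 1667 and 1653. RAD21, SMC3 and CTCF shared both regions under control siRNA, and of these CTCF alone had a peak at either region under RAD21 siRNA. SMC3 was retained on chromosome 15 from 61171918 to 61173876. It was lost on chromosome 11 from 117321899 to 117324034, with −10 × log10 p of 3233 in the control, while RAD21 and CTCF peaks were found there under both siRNAs. On chromosome 17 from 36956679 to 36960344, SMC3 was likewise lost where RAD21 and CTCF peaks were found under both.

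CTCF was retained on chromosome 12 from 50703760 to 50707106, a region with control peaks of 9 targets. The strongest lost CTCF peak, on chromosome 11 from 99950652 to 99953641, had RAD21 and SMC3 peaks under both siRNAs. The second, on chromosome 16 from 80529823 to 80532986, had RAD21 under both and SMC3 under control siRNA. HNF4A was retained on chromosome 10 from 101342408 to 101346591, where H3K4me1 was found under both siRNAs. On chromosome 2 from 157616965 to 157618417, HNF4A, RAD21 and H3K4me1 had control peaks, and none of the 11 targets had a siRAD21 peak. HNF4A was also lost on chromosome 22 from 49268812 to 49271771, where CTCF and H3K4me1 were found under both siRNAs.

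KLF5 was retained on chromosome 22 from 43484005 to 43486804. It was lost on chromosome 19 from 13810455 to 13814387, where MYC and H3K4me1 were found under both siRNAs, and on chromosome 7 from 150452827 to 150455599, where RAD21, SMC3, CTCF and H3K4me1 were. MYC was retained on chromosome 3 from 52694842 to 52697340, with −10 × log10 p of 3100. Its strongest lost peaks lay on chromosome 3 from 185333676 to 185336973 and on chromosome 16 from 51643461 to 51647977, and H3K4me1 was found at both under both siRNAs. The strongest retained REST peak, on chromosome 5 from 155566893 to 155569916, had no peak of any other target under either siRNA. REST was lost on chromosome 2 from 209808399 to 209810520 and on chromosome 4 from 12255631 to 12257669, again without a peak of any other target. It was gained on chromosome 1 from 6226204 to 6230009, where RAD21, SMC3, CTCF and H3K4me1 were found under both siRNAs.

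Some regions had a peak under RAD21 siRNA with no control peak of the same target within 1000 bp. The strongest for RAD21 lay on chromosome 3 from 171422374 to 171423035, where NIPBL had the sole control peak and 6 targets had siRAD21 peaks. For SMC3 it lay on chromosome 5 from 40869641 to 40872191, with peaks of 4 targets under control siRNA and 8 under RAD21 siRNA. The strongest gained KLF5 peak lay on chromosome 14 from 20921094 to 20923179, also with 4 and 8 targets, and the strongest gained MYC peak on chromosome 22 from 40011112 to 40012706, with 1 and 7. CTCF was gained on chromosome 8 from 144535495 to 144539684 at −10 × log10 p of 2082. HNF4A was gained on chromosome 2 from 159022075 to 159023723, a region with no control peak of any target.

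The third comparison asked how CTCF and cohesin behaved where they shared sites. At 27720 control CTCF peaks that overlapped both RAD21 and SMC3 peaks, CTCF was found again under RAD21 siRNA at 78.1% (95% interval 77.6 to 78.6), RAD21 at 57.8% (57.3 to 58.4) and SMC3 at 37.9% (37.4 to 38.5). CTCF was found with neither cohesin subunit at 23.4% of these sites, whereas a cohesin subunit without CTCF was found at 6.25%. All of the proteins were found at 33.0% and none at 15.6%. The ChIP tag ratio of siRAD21 to control was 0.346 for CTCF, 0.615 for RAD21 and 0.531 for SMC3, and that of the IgG libraries was 0.841 for CTCF and 0.460 for both cohesin subunits. The shares at these sites were not compared at like peak strength. Over all peaks matched by p, the retained share of CTCF exceeded that of RAD21 by 9.27 percentage points by overlap and 6.39 by summits. It exceeded that of SMC3 by 25.5 and 22.9.

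Cohesin peaks at CTCF sites were retained more often than cohesin peaks elsewhere. RAD21 kept 54.6% of 29826 peaks that overlapped CTCF and 9.39% of 6378 that did not. SMC3 kept 34.9% of 30507 and 4.29% of 8292. Much of this gap went with peak strength. It was 45.2 percentage points for RAD21 and 30.6 for SMC3 without strata, but compared within 5 strata of p the difference was 9.79 percentage points for RAD21 (95% interval 8.78 to 10.8) and 4.10 for SMC3 (3.45 to 4.75). It was 16.7 and 7.62 where CTCF-bound peaks were limited to those with a CTCF peak under both siRNAs, and 8.72 and 3.39 with 20 strata.

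The fourth comparison asked whether factor peaks at cohesin sites were lost more often than those elsewhere. Factors differed in both size and sign. MYC kept 23.7% of 4465 RAD21-bound peaks and 31.5% of 9124 RAD21-free peaks, a difference at like strength of −9.29 percentage points (95% interval −10.8 to −7.82). NIPBL had a difference of −9.20 (−10.5 to −7.87). HNF4A had −3.30 (−4.99 to −1.62), REST −3.63 (−6.80 to −0.456) and KLF5 −1.99 (−3.39 to −0.578). CTCF had 2.02 (0.95 to 3.10), JUND 2.71 (−0.174 to 5.59) and RFX2 0.449 (−3.54 to 4.44). The CTCF value depended on the strata, with −0.0478 (−1.12 to 1.03) for 20 strata of p, −1.69 (−2.98 to −0.406) for control peaks with an FDR under 5%, 38.6 (37.7 to 39.5) without strata and 12.8 (11.7 to 13.9) for strata of fold enrichment, where HNF4A had 0.250 (−1.57 to 2.07). REST had 0.342 (−1.35 to 2.03) for control peaks with an FDR under 5% and −3.14 (−6.69 to 0.402) with strata of fold enrichment, and KLF5 had −1.07 (−2.52 to 0.373) with the latter and −0.426 (−1.89 to 1.03) without strata. HNF4A had 1.52 (−0.478 to 3.52) without strata and −6.48 (−8.48 to −4.49) without CTCF-overlapping peaks. JUND lay clear of 0 with strata of fold enrichment, at 5.78 (2.85 to 8.71), without strata, at 6.23 (3.29 to 9.17), without CTCF-overlapping peaks, at 4.89 (1.38 to 8.39), and with cohesin taken from RAD21 and SMC3 together, at 3.72 (0.494 to 6.95). It had 0.832 (−2.27 to 3.93) without regions that held control peaks of 8 or more targets. RFX2 had 4.60 (0.175 to 9.03) without strata and −2.14 (−9.13 to 4.85) without CTCF-overlapping peaks.

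Over the 7 factors the median difference was −1.99 percentage points, with 3 above 0 and 4 below, and the exact two-sided sign-flip permutation test of the mean gave p = 0.281 (n = 7, smallest possible p 0.0156). The median was 1.52 without strata (exact p = 0.531, n = 7) and 0.250 with strata of fold enrichment (exact p = 0.703, n = 7). It was −3.75 without CTCF-overlapping peaks (exact p = 0.156, n = 6) and −2.09 for control peaks with an FDR under 5% (exact p = 0.0625, n = 6). In each of the latter settings 5 factors lay below 0 and 1 above. Leaving out HNF4A, MYC or REST gave a median of −0.768.

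The fifth comparison looked within RAD21-bound factor peaks and asked whether factor peaks were retained where RAD21 itself was retained. All 7 factors had a higher retained share there. CTCF kept 89.9% of 16291 peaks where RAD21 was retained and 58.2% of 13398 where RAD21 was lost, a difference at like strength of 11.9 percentage points (95% interval 10.9 to 12.8). HNF4A differed by 15.4 (12.0 to 18.8), JUND by 13.8 (8.50 to 19.1) and MYC by 13.1 (10.6 to 15.6). MYC kept 32.0% of its peaks where RAD21 was retained and 18.9% where it was lost. KLF5 differed by 3.61 (1.07 to 6.14). The intervals for RFX2, 5.46 (−2.02 to 12.9), and REST, 3.56 (−2.42 to 9.54), reached below 0. Some of these sizes moved with the choice of peaks or strata. JUND differed by 29.4 and MYC by 24.5 with strata of both the factor peak and the RAD21 peak, and by 41.6 and 28.7 without CTCF-overlapping peaks. CTCF differed by 31.7 without strata. KLF5 differed by 6.41 with strata of both peaks, by 6.70 without CTCF-overlapping peaks and by 2.51 (−0.124 to 5.14) without strata. REST differed by 7.15 (−0.166 to 14.5) with strata of both peaks and by 0.904 (−5.51 to 7.32) where SMC3 in place of RAD21 was retained.

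Over the 7 factors the median difference was 11.9 percentage points and the mean 9.54, with 7 of 7 above 0, and the exact two-sided sign-flip permutation test gave p = 0.0156 (n = 7), the smallest that 7 factors allow. SMC3 differed by 32.6 (31.5 to 33.7), NIPBL by 3.88 (1.85 to 5.90) and H3K4me1 by 1.99 (0.664 to 3.32). For H3K4me1 the plain shares ran the other way, with 77.9% retained where RAD21 was retained and 83.8% where it was lost. The difference was not particular to RAD21. Pairs of the 6 factors other than CTCF, with one factor's peaks split by whether the other was retained, had a median difference of 10.9 over 25 ordered pairs, against 9.27 for RAD21 over the same 6 factors and 11.9 over all 7.

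**Figure D3:**
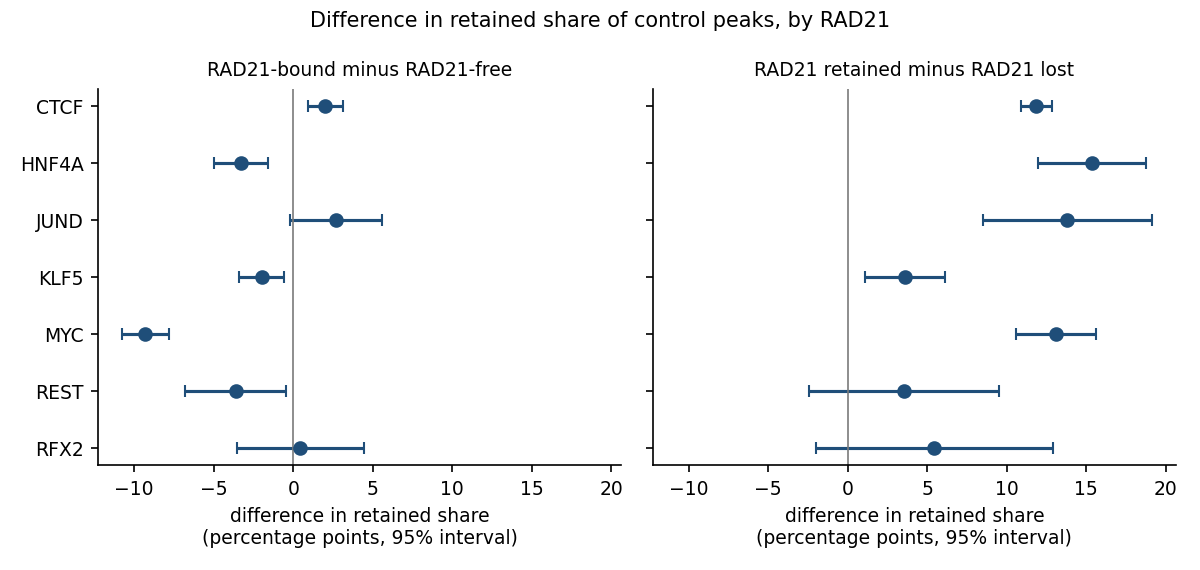
Difference in retained share for each of the 7 factors, in percentage points, averaged over 5 strata of p, with 95% intervals for counting error. Left, peaks with a control RAD21 peak minus those without, where values lie on both sides of 0. Right, RAD21-bound peaks where RAD21 was retained minus those where it was lost, where all 7 values lie above 0.

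The sixth comparison asked how often each target shared its sites with cohesin under control siRNA. RAD21 overlapped 81.6% of the SMC3 peaks (95% interval 81.2 to 81.9, chance 3.91%), 67.4% of the CTCF peaks (67.0 to 67.9, chance 4.01%) and 40.5% of the NIPBL peaks (39.6 to 41.4, chance 3.43%). JUND, MYC, KLF5 and HNF4A formed a middle range, with 33.0%, 32.9%, 29.6% and 26.3% of their peaks overlapping RAD21 and chance values of 3.65%, 4.32%, 4.14% and 3.98%. RFX2 had 15.2% (chance 3.22%) and REST 9.39% (8.51 to 10.3, chance 4.63%). With summits within 250 bp in place of overlap, HNF4A had 15.8%, JUND 21.3%, KLF5 18.7%, MYC 21.3%, RFX2 6.54% and REST 4.28%, whereas CTCF had 65.3%.

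H3K4me1 divided the targets in another way. It overlapped 87.8% of the HNF4A peaks, 86.1% of the MYC peaks, 83.2% of the NIPBL peaks, 80.5% of the JUND peaks and 78.2% of the KLF5 peaks. RFX2 had 43.6%, SMC3 34.1% and CTCF 25.4% (chance 9.64%). REST had 14.7% (13.6 to 15.8), close to its chance value of 10.6%.

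The last comparison asked whether dense clusters of factors coincided with cohesin. The 43327 control peaks of HNF4A, JUND, KLF5, MYC, REST and RFX2 formed 30255 clusters. A RAD21 peak was found at 17.5% of the 21979 clusters with 1 factor (95% interval 17.0 to 18.0, chance 4.0%), 33.7% of the 5638 with 2 (32.4 to 34.9, chance 4.89%), 47.8% of the 2069 with 3 (45.7 to 50.0, chance 5.55%) and 62.2% of the 569 with 4 or more (58.1 to 66.2, chance 6.61%). The share over chance was 4.37 for 1 factor and 9.41 for 4 or more, although wider clusters also had higher chance values. Without JUND, whose control list held no peak with an FDR under 5%, 75 clusters with 4 or more factors were left, and RAD21 was found at 56.0% of them (44.1 to 67.5), an interval that covered the 52.8% of clusters with 3 factors. For peaks with −10 × log10 p of at least 100 the class of 4 or more held 61 clusters, at 70.5% (57.4 to 81.5) against 60.4% with 3.

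The share of clusters that lost all their peaks under RAD21 siRNA was lower in classes with more factors. All control peaks were lost at 68.3% of the clusters with 1 factor, 53.7% with 2, 41.5% with 3 and 27.9% with 4 or more. More peaks per cluster give more chances to keep one, and the retained share per peak was 31.5%, 28.1%, 29.5% and 33.3% in the same order. These shares pool factors in unlike proportions. Of the 22509 peaks in clusters with 1 factor, 3591 were REST peaks, of which 70.3% were retained. By plain shares, HNF4A, JUND, KLF5 and RFX2 peaks were retained more often in clusters of at least 2 factors than alone, and MYC and REST peaks less often. A cluster of 5 factors on chromosome 17 from 46059845 to 46072517 had 8 peaks, of which 3 were retained, and RAD21, SMC3 and CTCF were found there under both siRNAs. One on chromosome 10 from 132610747 to 132619919 also had RAD21 under both siRNAs, SMC3 under control siRNA and no CTCF, and kept 3 of its 6 peaks. The other named clusters had no RAD21 peak under either siRNA, though some had SMC3 or CTCF peaks. The cluster on chromosome 20 from 1253138 to 1258814 kept 5 of 7 peaks and had SMC3 under both siRNAs. That on chromosome 19 from 13810455 to 13820874 kept 3 of 7, with SMC3 under control siRNA and CTCF under both. That on chromosome 10 from 95296633 to 95301451 kept 2 of 6 and had neither SMC3 nor CTCF.

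**Figure D4:**
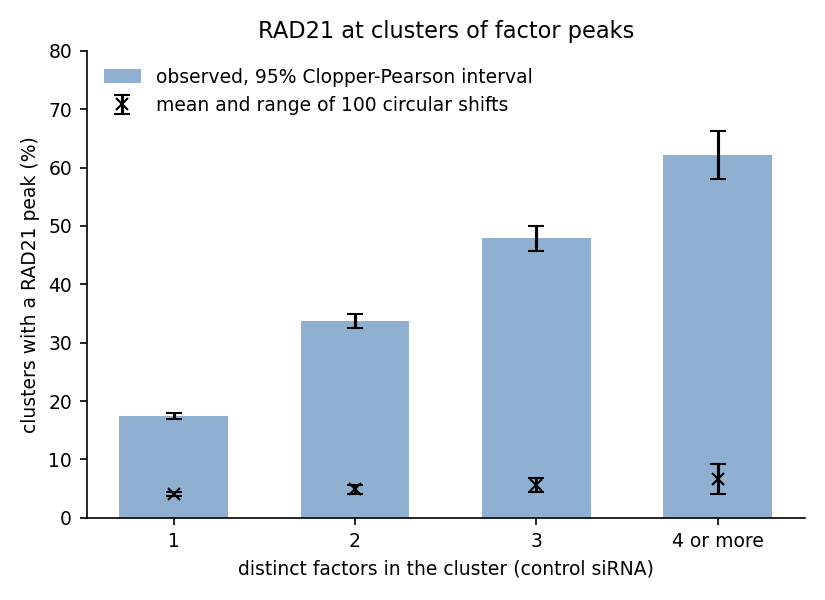
Share of control factor clusters with a control RAD21 peak, in percent, by the number of distinct factors in the cluster (bars, with 95% Clopper-Pearson intervals), and the mean and range of 100 circular shifts (crosses). The share is 17.5% with 1 factor and 62.2% with 4 or more.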

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

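The tests of depth across targets, of depth for RAD21 and SMC3, of single immunoprecipitations and of the IgG libraries were chosen only after the results were seen, as was the use of the 6-factor value as a second yardstick for the pairs of factors.

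JUND and REST stood apart because their siRAD21 libraries held more peaks than their control libraries, with ratios of 2.63 and 1.07, while the other 9 targets had fewer. The difference between these targets and the others was not tested. The siRAD21 JUND library had 2.02 times the tags of its control, and the lowest FDR in the control JUND list was 9.19%, against 1.86% in the siRAD21 list.

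Fewer peaks after RAD21 siRNA may reflect lower sequencing depth. Over the 11 targets, the log ratio of peak numbers and the log ratio of tags gave a Spearman coefficient of 0.382 (permutation p = 0.249, 95% interval −0.283 to 0.799) and a Pearson r of 0.694 (permutation p = 0.0441). Pearson's r was 0.405 without JUND and MYC, the targets farthest from the median tag ratio. These were left out together, so their parts in the linear relation were not separated. Without JUND alone, the Spearman coefficient was 0.176 over 10 targets. MYC had a tag ratio of 1.02 and a peak ratio of 0.535. Depth and RAD21 siRNA cannot be told apart as sources of the lower peak numbers, because 11 targets leave a wide interval and both moved in the same direction in 9 of them.

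Among all peaks RAD21 had the fourth highest retained share of the 11 targets. At like control peak strength by p, REST exceeded RAD21 by 21.7 percentage points (95% interval 20.4 to 22.9) and SMC3 by 37.9 (36.6 to 39.1). The tag ratios of REST, RAD21 and SMC3 were 0.619, 0.615 and 0.531, with the same IgG libraries. By overlap every target compared exceeded SMC3, with KLF5 nearest at 3.07 (1.12 to 5.02). The match used p, which depends on depth, and the control libraries held 6787207 tags for REST, 14724408 for RAD21 and 17138940 for SMC3. For SMC3 these gaps argue against depth as the whole cause, as far as p measures strength alike in libraries of unlike depth. By summits within 250 bp REST still exceeded SMC3 by 33.3 and H3K4me1 by 14.2, although KLF5 did not, at −0.469 (−2.53 to 1.59). For RAD21 lower depth cannot be told apart from the siRNA, because the order turned with the measure for some targets. H3K4me1 minus RAD21 was 26.7 by overlap and −3.61 (−4.16 to −3.07) by summits. MYC minus RAD21 was 5.48 and −1.94, and NIPBL minus RAD21 0.493 and −2.40. REST, JUND, CTCF and HNF4A lay above RAD21 by both measures, with REST at 16.8 and CTCF at 6.39 by summits. KLF5 lay below RAD21 by both, at −18.1 by summits. With equal numbers of the strongest peaks, which does not match strength, H3K4me1 kept 78.9%, CTCF 77.8%, RAD21 73.0%, REST 68.3% and SMC3 64.4%. HNF4A kept 45.6%, MYC 41.0%, KLF5 25.9%, NIPBL 24.3%, RFX2 21.4% and JUND 17.6%. Variation between single immunoprecipitations cannot be told apart from an effect of the siRNA, because there was 1 library per target and siRNA, and a lower occupancy of cohesin after RAD21 siRNA stays a hypothesis beside it.

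Factor peaks were retained more often where RAD21 was retained, by a median of 11.9 percentage points. The strength of the RAD21 peak is argued against as a whole cause, since the median was 10.3 with strata of both peaks (exact permutation p = 0.0156, n = 7). Without regions that held control peaks of 8 or more targets the median was 11.3 (exact permutation p = 0.0156, n = 7). This argues against those regions as the whole cause, but not against regions shared by fewer targets, which stayed in. Where RAD21 was retained, 16144 of 16291 CTCF peaks and 301 of 400 JUND peaks were still counted. The rabbit IgG library shared with RAD21 is argued against for CTCF, which was called against goat IgG and differed by 11.9 (10.9 to 12.8), but for the other factors it cannot be told apart, since RFX2, also called against goat IgG, differed by 5.46 (−2.02 to 12.9). A general tendency of co-located peaks to be called together could account for the pattern and cannot be told apart from a link to cohesin, since the median over pairs of other factors was 10.9, above the RAD21 value of 9.27 over the same 6 factors and below that of 11.9 over all 7. An effect of cohesin on the factors stays open as a hypothesis that these data do not separate from chromatin that is easier to recover.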

How the results depend on the processing

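Alternatives with 20 strata, with strata within the RAD21-bound peaks, with strata of both peaks, without regions of 8 or more targets, without JUND and NIPBL, and leaving out single factors other than CTCF were chosen after seeing the data. The higher retained share of factor peaks where RAD21 was retained kept its direction and its side of the threshold in all 14 alternatives run. Its medians ran from 8.66 to 15 percentage points. The difference between RAD21-bound and RAD21-free factor peaks did not pass the threshold in any of its 14 alternatives. Its median of −1.99 turned to 1.52 without strata and to 0.250 with strata of fold enrichment. It stayed below 0 in the other alternatives, at −3.75 without CTCF-overlapping peaks and −2.09 for control peaks with an FDR under 5%. Leaving out single factors could not move either result across the threshold, so those alternatives add no support. All 7 main values of the RAD21-retained difference lay above 0, and those of the RAD21-bound difference had mixed signs. The siRAD21 libraries held fewer filtered tags for 9 of 11 targets, and no comparison at equal depth was made. JUND and NIPBL have no ratio or retained share at an FDR under 5%, since no control peak passed it, while 718 and 1441 of their siRAD21 peaks did. The cause was not tested for any of the shifts that follow. Of the peak count ratios, REST turned to 0.898 for peaks with −10 × log10 p of at least 100, and H3K4me1 and RFX2 turned to 1.29 and 1.28 at an FDR under 5%. At −10 × log10 p of at least 100 the ratio was 0.183 for SMC3, 4.39 for JUND and 0.0990 for KLF5. At an FDR under 5% it was 0.114 for SMC3, 0.125 for KLF5 and 0.0689 for MYC.

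Retained shares moved beyond their counting intervals in 50 of 53 alternatives. At an FDR under 5% in both lists they were 37.7% for RAD21, 11.2% for SMC3, 75.2% for CTCF, 86.2% for H3K4me1, 45.6% for HNF4A, 6.64% for KLF5, 6.15% for MYC, 96.5% for REST and 28.5% for RFX2. For control peaks with −10 × log10 p of at least 100 they were 61.7% for RAD21, 39.6% for SMC3, 32.2% for NIPBL, 75.5% for CTCF, 83.6% for H3K4me1, 54.3% for HNF4A, 56.4% for JUND, 21.3% for KLF5, 46.0% for MYC, 90.8% for REST and 39.1% for RFX2. With equal numbers of the strongest peaks they were 73.0% for RAD21, 64.4% for SMC3, 24.3% for NIPBL, 77.8% for CTCF, 78.9% for H3K4me1, 45.6% for HNF4A, 17.6% for JUND, 25.9% for KLF5, 41.0% for MYC and 21.4% for RFX2. With at least 50% of the control peak covered they were 42.2% for RAD21, 25.5% for SMC3, 15.8% for NIPBL, 58.9% for CTCF, 71.9% for H3K4me1, 30.2% for HNF4A, 6.33% for KLF5, 25.2% for MYC, 64.2% for REST and 9.82% for RFX2. With summits within 250 bp they were 45.6% for RAD21, 27.1% for SMC3, 14.0% for NIPBL, 59.3% for CTCF, 42.6% for H3K4me1, 29.4% for HNF4A, 27.4% for JUND, 8.02% for KLF5, 22.6% for MYC and 64.5% for REST.

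The gap between CTCF-bound and CTCF-free peaks was 45.2 percentage points for RAD21 and 30.6 for SMC3 without strata, 16.7 and 7.62 with a CTCF peak under both siRNAs, and 8.72 and 3.39 with 20 strata. The overlap with RAD21 by summits within 250 bp was 65.3% for CTCF, 15.8% for HNF4A, 21.3% for JUND, 18.7% for KLF5, 21.3% for MYC, 4.28% for REST and 6.54% for RFX2. At an FDR under 5% it was 74.4% for CTCF, 22.1% for HNF4A, 24.1% for KLF5, 25.8% for MYC, 7.83% for REST and 16.9% for RFX2. With SMC3 in place of RAD21 it was 68.8% for CTCF, 29.5% for HNF4A, 37.9% for JUND, 37.8% for KLF5, 39.1% for MYC, 10.9% for REST and 18.2% for RFX2. The share of clusters with RAD21 for 1, 2, 3 and 4 or more factors was 22.3%, 43.8%, 60.4% and 70.5% for peaks with −10 × log10 p of at least 100, and 18.5%, 36.1%, 52.8% and 56.0% without JUND.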

Other observations

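The comparisons of gained peaks and of peaks in and outside clusters were chosen only after the data were seen, and no test between libraries was made. Peaks found under RAD21 siRNA with no control peak of the same target within 1000 bp differed in their company from peaks that had one. The shares of gained peaks given here and below were not compared at like strength, although weak control peaks were retained less often than strong ones. Peak strength was therefore not separated from being gained. For RAD21, 68.5% of 2584 gained peaks overlapped a siRAD21 H3K4me1 peak, against 26.9% of 17168 peaks that had a control peak. SMC3 showed 60.1% of 1364 against 29.0% of 11184, CTCF 58.4% of 3810 against 27.1% of 28386, and REST 41.4% of 1460 against 13.7% of 2900. For the factors that lay mostly within H3K4me1 the order was the opposite, with 75.9% of gained and 92.1% of other peaks for HNF4A, 62.4% and 94.4% for KLF5, 74.9% and 92.8% for MYC, 86.6% and 92.8% for JUND, and 82.1% and 89.2% for NIPBL. RFX2 had 41.6% and 79.4%.

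The share of siRAD21 peaks that coincided with siRAD21 peaks of at least 2 other targets, H3K4me1 not counted, was lower for gained peaks than for those with a control peak in 7 of 10 targets and higher in 3. REST had 24.5% (95% interval 22.3 to 26.7) against 6.21% (5.36 to 7.15), JUND 46.3% against 41.6%, and HNF4A 47.6% (45.9 to 49.4) against 27.6% (26.2 to 29.1). Among the 7, SMC3 had 45.5% against 86.8%, RFX2 21.8% against 50.9%, RAD21 50.9% against 59.6%, CTCF 26.3% against 38.4%, NIPBL 59.9% against 66.1%, KLF5 38.9% (35.8 to 42.1) against 60.4% (57.0 to 63.7) and MYC 47.6% (45.8 to 49.3) against 66.7% (65.2 to 68.1).

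Among pairs of factors, MYC and JUND had the widest gap. JUND peaks that overlapped a retained MYC peak were retained more often than those that overlapped a lost one, by 43.4 percentage points at like strength (39.4 to 47.4), and HNF4A peaks split by MYC differed by 30.7 (27.1 to 34.3). Peaks in clusters of at least 2 factors and peaks alone differed by factor. JUND kept 43.4% of its peaks in clusters and 20.8% of those alone, a difference at like strength of 18.0 (15.3 to 20.7), whereas MYC kept 27.1% and 30.9%, a difference of −7.16 (−8.58 to −5.73). Over the 6 factors the median difference was 1.85, and the exact sign-flip permutation test gave p = 0.531 (n = 6, smallest possible p 0.0313).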
